A study of Mus musculus with 56 samples.

How the data were processed

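RNA was measured in mouse fibroblasts that carry an Oct4-GFP reporter and were reprogrammed with Oct4, Sox2, Klf4 and Myc. Per the submitters' processing notes, reads were trimmed with Trim Galore, checked with FastQC and counted with RSEM. Versions were not given. The genome was GRCm38 (mm10) for 54 samples and mm9 for 2, an embryonic fibroblast (MEF) library and an induced pluripotent stem cell (iPSC) library. Of 56 samples, 4 day 10 shRNA samples have no column of their own in the deposited tables.

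The day 10 overexpression table holds 6 libraries in 3 groups, and the sorted-cell table holds 44 libraries in 22 groups of 2. The unit of both, here called a score, is a tag count that the authors normalized so that all libraries of a table share nearly the same distribution, and then rounded. This was read from the values, since the labels do not name the normalization. Library totals ran from 19465402 to 19479768 in the first table and from 31777102 to 31798964 in the second, with medians of 599 and 500. Levels were compared only within a table. The deposited MEF and iPSC table holds whole-number counts that the authors left without scaling between the libraries. Its totals were 16593659 and 9912018. The score, log2 and p-value columns of the authors' 2 deposited comparison tables stand without a header: condition means floored at 0.5, the log2 ratio of these means, and a p whose adjustment is not stated. These columns were identified from their arithmetic. Which mean is which condition is not given, so directions are stated relative to Ctcf in the same table.

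Normalized scores cannot be modelled as counts, so limma 3.58.1 in R 4.3.3 was fitted to log2(score + 1) with a mean-variance trend and 1 coefficient per group. Genes with a score of at least 10 in at least 2 libraries were tested, a filter that every gene met. These were 12935 genes in the overexpression table and 13451 in the sorted-cell table, of which 12935 and 13447 matched the annotation. Repeat types were fitted apart from genes. A gene is called at an adjusted p (Benjamini-Hochberg) below 0.05, and SE is the moderated standard error. Residual degrees of freedom were 2 and 22. Levels are means with standard deviations of n = 2 libraries unless stated. The p-values of these fits measure only the spread between samples. That spread may be technical, because the labels do not say whether replicates came from separate cultures.

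The 2 control columns of the overexpression table differ by 0.319 to 0.528 of the spread that counting alone would give if scores were counts. The other 24 replicate pairs differ by 1.41 to 95.2 times that spread. Scores are normalized, so this does not show a spread below that of counting, only a smaller one than in the other pairs. The control columns were averaged and counted as 1 sample, a choice made after these values were seen. The plan had kept all 6 libraries of that table in 1 fit. The labels give replicate numbers no shared meaning across groups, and the numbers were not used as pairs.

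Before the data were examined, these were fixed: the sample groups, the comparisons, the model, the gene filter, the thresholds, the gene lists, the rule for named genes and the first set of alternatives. The lists hold pluripotency, reprogramming factor, fibroblast matrix, mesenchymal, epithelial, CTCF/cohesin/ISWI, cell cycle, p53, AP-1, interferon, clustered protocadherin, Hox, imprinted, trophoblast, endoderm, neural, keratinocyte, smooth muscle, skeletal muscle, macrophage and endothelial genes. MEF-high and iPSC-high lists are the 200 genes with the largest ratio either way in the study's own 2 libraries, so they are not independent of the study. Two-cell-stage and mitochondrially encoded genes were also planned, and had fewer than 3 tested members. A list was tested with camera at an inter-gene correlation of 0.01, and again with the correlation estimated from the data. Camera p was adjusted over the lists of a comparison. Alpha and gamma protocadherins share constant exons and have nearly equal values. Protocadherin counts and list p-values throughout therefore do not rest on separate measurements, and the p-values are too small. In the MEF and iPSC table and the authors' tables, where no replicate fit was possible, a list median is placed among 10000 random lists of the same size and level. Members were also counted after p was adjusted over the list alone.

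Named genes follow a fixed rule. Ctcf and Smarca5 are given everywhere, and the 4 factors in each comparison fitted here. Past adjusted p, the largest log2 fold changes per direction are named: 8 at day 10, 10 for the mean knockdown effect and for day 12 against day 0, and 5 for SSEA1+ against Thy1+ cells. Their higher group mean lies at or above the median and their libraries do not overlap. For the mean effect at least 10 of 11 populations must move the same way. Predicted, pseudogene and clone symbols are left out, and some genes that meet the rule are not reported here. The 6 interaction genes with the smallest p are named, and per list at most 4 members with the smallest adjusted p. Counts of 5 or fewer outside this rule are named as genes chosen after their values were seen. Coordinates are GRCm38, from the annotation.

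The alternatives fixed first were no gene filter, quantile normalization, a pseudocount of 8 (0.1 for MEF and iPSC counts), no trend, omission of each library, a replicate block, and for lists the estimated correlation. Others were added after the data were seen: a mean level of at least 100, 2 groups fitted alone, omission of populations or days, a replicate block for lists, and a stricter p in the authors' tables. The fit with separate control columns, which was the planned one, is given as an alternative. The stricter level keeps 12525 of 12935 and 11198 of 13451 genes. Label splits exchanged control and Ctcf shRNA labels within populations 100 times, the real labels included. In simulated data with 100 changed genes per size, a log2 change of 1 was recovered for 99% of genes in the mean effect, 81% at day 12, 85% in the SSEA1+ against Thy1+ difference, 45% in the interaction and 4% in the overexpression contrast, where a change of 2 was recovered for 37%. A log2 change of 0.5 was recovered for 85%, 50%, 61% and 6% in the first 4 of these. A list of 28 genes shifted by 0.3 was called in 100 of 100 simulated sets, and an unshifted list in 0. Simulated genes varied independently, so this does not give the error rate for lists whose genes are correlated. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

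Isoforms, reads and binding or chromosome contact data were not analysed here. The 4 day 10 shRNA samples were not tested here, and their comparison is described from the authors' deposited table only. Sequences of the delivered factors were not separated from the genes of the cell.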

Results

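Mouse fibroblasts with an Oct4-GFP reporter were sampled on the way to pluripotent cells under changed levels of the insulator protein CTCF. Doxycycline-induced cells with control shRNA or Ctcf shRNA were taken at day 0, sorted at days 3, 6 and 9 into Thy1+, SSEA1+ and double-negative (DN) cells, and sorted at day 12 for GFP. These are 11 populations with 2 libraries per shRNA. At day 10, cells with retroviral factors carried a control vector, CTCF overexpression, or CTCF overexpression with an shRNA against the chromatin remodeller Smarca5. Thy1 marks fibroblasts, SSEA1 an intermediate state and Oct4-GFP the late pluripotent state.

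Ctcf (GRCm38 8:105636568-105682922) stood at 1248 in the day 10 control sample, at 5621 ± 723 with overexpression and at 6215 ± 1428 with the added Smarca5 shRNA. Smarca5 (GRCm38 8:80698507-80739497), the ATPase of ISWI remodelling complexes, stood at 11916, 13550 ± 378 and 6518.5 ± 186. In the sorted table, control against Ctcf shRNA gave Ctcf scores of 810 ± 28.3 and 568 ± 67.9 at day 0, and at day 3 868 ± 58.0 and 512.5 ± 34.6 (Thy1+), 1397.5 ± 50.2 and 788 ± 67.9 (SSEA1+), and 1125.5 ± 48.8 and 568 ± 2.83 (DN). At day 6 they were 833.5 ± 24.7 and 441.5 ± 29.0 (Thy1+), 1959.5 ± 48.8 and 851.5 ± 19.1 (SSEA1+), and 1474.5 ± 12.0 and 561 ± 29.7 (DN). At day 9 they were 942 ± 24.0 and 403.5 ± 19.1 (Thy1+), 1717.5 ± 192 and 709.5 ± 10.6 (SSEA1+), and 1359 ± 26.9 and 543.5 ± 60.1 (DN). Day 12 GFP+ cells had 2411 ± 42.4 and 686 ± 17.0, each n = 2. Smarca5 scores of the sorted table are unusually high: 94553 ± 3791.5 in day 0 control cells, above Col1a1 at 32906 ± 4296.4. In the authors' deposited day 10 overexpression table Smarca5 had 4119 and Col1a1 10072 in the condition with less Ctcf. What reads make up the sorted score was not examined. Smarca5 fold changes of the sorted table may therefore not be those of its transcript alone.

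Ctcf fell with its shRNA in every population. The log2 fold change was -0.52 at day 0 (SE 0.09, adjusted p = 0.000621), -0.76, -0.83 and -0.98 in Thy1+, SSEA1+ and DN cells of day 3, -0.92, -1.20 and -1.39 at day 6, -1.22, -1.27 and -1.32 at day 9, and -1.81 at day 12 (adjusted p = 5.89e-15). Smarca5 stood at 0.30 at day 0 (adjusted p = 0.106), -0.03, -0.03 and 0.09 in Thy1+, SSEA1+ and DN cells of day 3, -0.11, -0.29 and -0.27 at day 6, -0.16, -0.02 and -0.25 at day 9, and -0.28 at day 12 (adjusted p = 0.0421), its only call. Single libraries decide that: it ends without D12_shLuci_GFP+ replicate 2 (adjusted p = 0.195), while Smarca5 passes at day 0 without D0_shCTCF replicate 1 (0.39, adjusted p = 0.0469) and in day 6 SSEA1+ cells without D6_shLuci_SSEA1+ replicate 1 (-0.42, adjusted p = 0.0411).

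**Figure D1:**
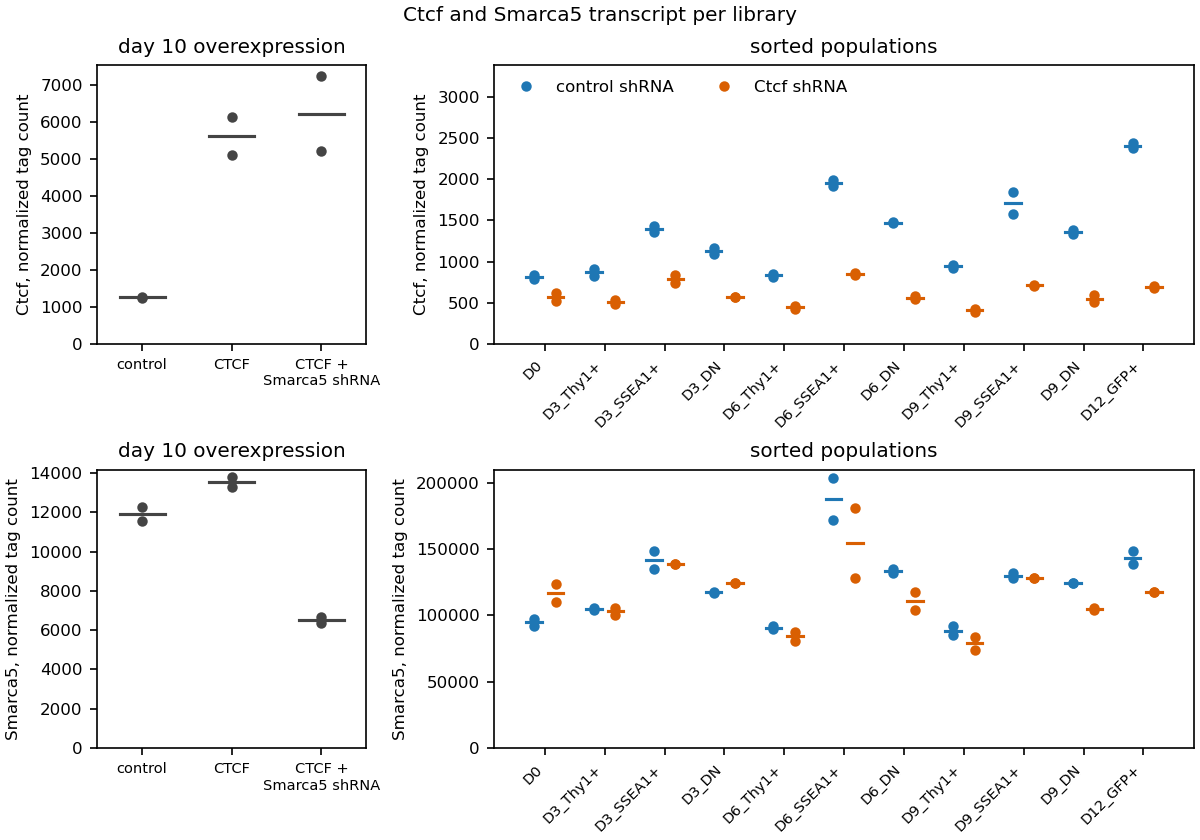
Ctcf and Smarca5 scores per library in each group of the 2 tables, with control and Ctcf shRNA side by side. Day 12 GFP+ cells had the highest control level of Ctcf, 2411.

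With control shRNA, reprogramming took fibroblasts to cells with a pluripotency program. Dppa5a rose from 0.5 at day 0 to 7746 at day 12 (log2 12.41), with Tdgf1 (12.33), Utf1 (11.93), Esrrb (11.54) and the zinc finger gene Zfp600 (11.52). Dazl, Hormad1, Mcf2, Lin28a and Slco4c1 rose from cells in which they were listed at 0. Dazl and Hormad1 act in germ cells, and Lin28a blocks let-7 maturation. In the other direction Tfpi2, an inhibitor of matrix proteases, fell from 2746 to a level listed at 0, as did Wincr1, Prl3a1, Uts2b, Prl8a6, Lce1h, Tmprss11f and U90926, and Ptgs2os2 (-10.45, antisense to Ptgs2) and S100a7a (-9.98) fell too. Ctcf rose by 1.57 (SE 0.09) and Smarca5 by 0.60, and the factors Pou5f1, Sox2, Klf4 and Myc by 5.39, 4.37, 2.21 and 1.93, transgene reads included.

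All 28 pluripotency genes rose from day 0 to day 12 (28 also adjusted over the list alone), with a median of 9.41. Among them L1td1 went from 4.5 to 5268.5 (log2 9.91), and Fgf4, Tet1 and Mybl2 rose by 10.53, 7.60 and 4.30. Epithelial genes went the same way, 19 higher and 1 lower of 20 (median 6.10), with Esrp1 at 9.98, Cldn4 at 6.61, Krt8 at 5.94 and St14 at 4.88. Fibroblast matrix genes fell, 20 of 20 (median -2.77), among them Lox (-5.67), the enzyme that crosslinks collagen, Col5a2 (-4.76), Fbln2 (-3.81) and Loxl2 (-3.16). Mesenchymal genes had 1 higher and 18 lower of 19 (Prrx1 -4.05, Vim -3.42), smooth muscle genes 9 lower of 9 (Tagln -5.44, Acta2 -5.39), Hox genes 30 lower of 30 (median -3.77) and clustered protocadherins 28 lower of 28 (-1.70). Cell cycle genes had 18 higher and 1 lower (19 and 1 adjusted over the list alone; median 1.50). Of the CTCF, cohesin and ISWI genes 16 rose and 0 fell (median 0.61), led by the cohesin subunit Rad21 (1.56) and Baz2a (2.84). The 4 keratinocyte genes rose (median 3.81). Here and below, where a list has no second count, the count adjusted over the list alone is the same.

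In all, 10792 genes were called between day 12 and day 0, 5388 higher and 5404 lower. List tests were called for pluripotency (adjusted p = 2.12e-13), epithelial (7.05e-09), matrix (4.74e-09, and adjusted p = 0.0648 with an estimated correlation), CTCF, cohesin and ISWI (0.000708, and adjusted p = 0.0648 with an estimated correlation), protocadherin (1.72e-09, and adjusted p = 0.126 with an estimated correlation) and keratinocyte genes (0.0304, and adjusted p = 0.0697 with an estimated correlation). No list call was made for imprinted genes, with 8 higher and 9 lower (median -0.12, adjusted p = 0.927), p53 genes, 4 and 7 (0.03, adjusted p = 0.435), or macrophage genes, 1 and 8 (-3.71, adjusted p = 0.116). MEF-high genes, chosen on the study's own libraries and therefore not independent, had 8 higher and 186 lower, and iPSC-high genes 183 and 1. Without D0_shLuci replicate 1 the Zfp600 fold is 8.93, and without D12_shLuci_GFP+ replicate 2 that of Ptgs2os2 is -8.32, since their lower levels are near 0.

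Within a day, SSEA1+ cells stood far ahead of Thy1+ cells. Nanog was 1606.5 ± 115 in day 6 SSEA1+ cells against 20 in Thy1+ cells (log2 6.26), with Nr5a2 (6.41), Sall4 (5.33), Esx1 (5.52) and Mobp (5.35) also higher. Col3a1, the type III collagen, stood at 240 against 24972 (-6.71), and Pdgfra (-7.15), Slc14a1 (-6.92), Ifi205 (-6.74) and Hgf (-6.67) were lower too. At day 3 the largest rises in SSEA1+ cells included Insm1 (3.53), Dpysl5 (3.26), the nuclear pore gene Nup210 (3.24, 2297 against 242), Foxd1 (3.21) and Plxnc1 (3.09), and the largest falls Cd53 (-6.29), Gpm6a (-6.25), Prl2c2 (-4.85, 440 against 12424) and Dhrs9 (-4.82). At day 9 they included Utf1 (3.90), Slco4c1 (3.86), Ap1m2 (3.73) and Cldn3 (3.60) against Acan (-4.05), Lrrc17 (-3.76), Pde3a (-3.68), Mylk (-3.64) and Il1r1 (-3.47). Ctcf was higher in SSEA1+ cells by 0.69, 1.23 and 0.86 at days 3, 6 and 9, and Smarca5 by 0.43, 1.04 and 0.56. The factors Myc, Pou5f1, Sox2 and Klf4 were higher by 1.29, 1.47, 1.48 and 1.59 at day 3, 1.93, 2.03, 1.89 and 1.76 at day 6, and 1.30, 1.45, 1.51 and 1.01 at day 9.

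The pluripotency list had 12 higher and 2 lower of 28 at day 3 (median 0.77), 22 and 2 at day 6 (2.37) and 26 and 2 at day 9 (2.85). Epithelial genes had 13 and 5 (1.25), 18 and 2 (2.91) and 20 and 0 (2.79). All 20 matrix genes were lower in SSEA1+ cells on each day (medians -3.47, -4.61 and -2.65), and so were the 9 smooth muscle genes (-3.99, -4.67 and -2.54). Cell cycle genes had 19, 20 and 20 higher of 20 (0.91, 1.59 and 1.23). Protocadherins had 25, 27 and 27 lower of 28 (medians -2.11 and -1.64 at days 6 and 9). At day 9, 28 protocadherins were lower when adjusted over the list alone.

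Called genes numbered 8636 at day 3, 10246 at day 6 and 9252 at day 9. The pluripotency test was called at day 3 (adjusted p = 0.0382, and adjusted p = 0.0544 with an estimated correlation), day 6 (0.000469) and day 9 (3.09e-06). Without D3_shLuci_SSEA1+ replicate 2 the Cd53 call is lost (-3.19, adjusted p = 0.145), and without D6_shLuci_SSEA1+ replicate 1 that of Ifi205 (-3.56, adjusted p = 0.0684). Near-zero levels also set 3 other folds: Gpm6a is -2.74 without D3_shLuci_SSEA1+ replicate 1, Hgf -4.44 without D6_shLuci_SSEA1+ replicate 2 and Nr5a2 5.78 without D6_shLuci_Thy1+ replicate 2.

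SSEA1+ cells were also set against day 0. Pluripotency genes had 14 higher and 4 lower of 28 at day 3 (13 and 4 adjusted over the list alone; median 1.04), 22 and 3 at day 6 (3.36) and 25 and 2 at day 9 (26 and 2 adjusted over the list alone; 6.15), and epithelial genes 15 and 2 (16 and 2 adjusted over the list alone; 2.55), 19 and 1 (5.70) and 19 and 0 (7.24). Matrix genes had 20 lower at days 3 and 6 (-3.54 and -4.30), and 1 higher and 16 lower at day 9 (-1.44, adjusted p = 3.08e-06, and adjusted p = 0.104 with an estimated correlation). Macrophage genes, from cells that accompany fibroblast cultures, had 1 higher and 9 lower of 10 on each day (medians -4.53, -5.06 and -4.77, adjusted p = 0.00868, 0.0146 and 0.0136). Ctcf rose by 0.79, 1.27 and 1.08 and Smarca5 by 0.58, 0.98 and 0.46. Pou5f1 rose by 5.71, 5.23 and 4.77, Sox2 by 5.12, 4.49 and 4.42, Klf4 by 3.77, 3.21 and 2.75 and Myc by 3.30, 2.95 and 2.61. Called genes numbered 9716, 10355 and 9807.

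**Figure D2:**
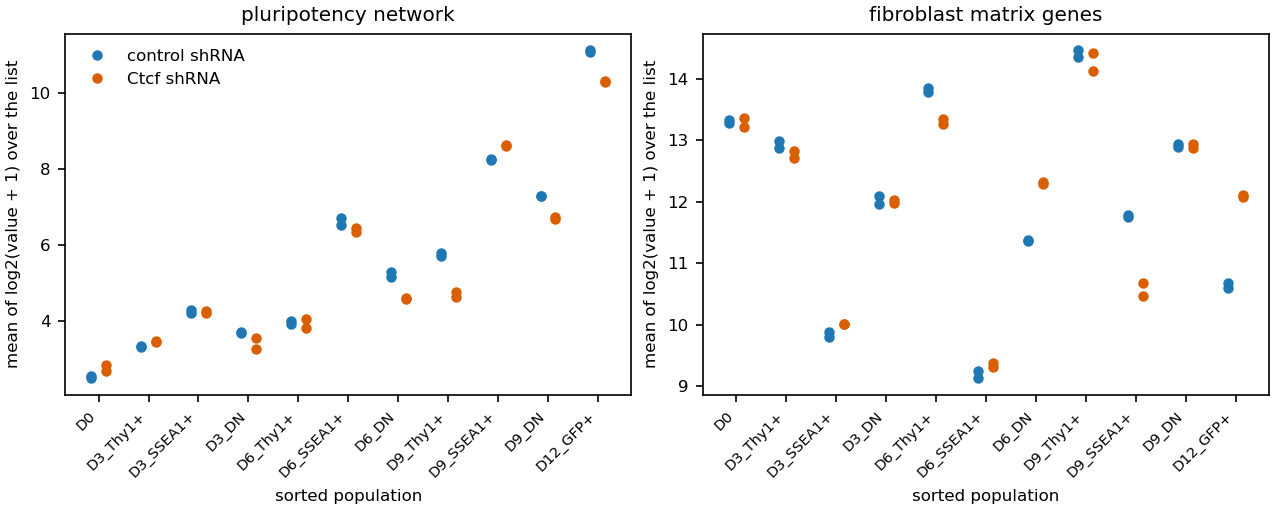
Mean log2 level of gene lists per library across days and sorted populations, with control and Ctcf shRNA side by side. Pluripotency genes stand a median of 9.41 above day 0 at day 12 with control shRNA.

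The MEF and iPSC libraries, 1 each, differ as these cell types do. Cdh1, the epithelial cadherin, had 1 read in MEFs and 39133 in iPSCs (log2 -11.86), and Nanog had 8 and 6158. Col1a1 had 263378 and 12815 (3.62), Cxcl12 34504 and 146 (7.05) and Acta2 75594 and 495 (6.48), while Thy1 stood at 3.11 and H19 at 4.70. Ctcf was lower in MEFs by -1.47, Smarca5 by -1.25, and Myc was higher by 1.09.

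At least 8-fold higher in iPSCs were 27 of 28 pluripotency genes (median -6.45), 14 of 20 epithelial genes (-4.57) and 2 of 4 factors (-4.52). Higher in MEFs to that degree were 13 of 20 matrix genes (3.58), 13 of 19 mesenchymal genes (3.12), 9 of 9 smooth muscle genes (5.35), 13 of 36 Hox genes (2.06), 4 of 6 macrophage genes (4.52) and 0 of 10 protocadherins (1.81). Imprinted genes had 6 higher in MEFs and 2 in iPSCs of 19 (1.02). Other medians were -1.73 for cell cycle, 1.20 for AP-1, 0.89 for interferon, 0.06 for p53, -0.83 for CTCF, cohesin and ISWI, -0.38 for trophoblast, 0.60 for endoderm, -0.85 for neural, -0.32 for keratinocyte, 1.59 for skeletal muscle and -1.39 for endothelial genes. Over all genes 682 were at least 8-fold higher in MEFs and 660 in iPSCs. With 1 library each there is no test, and with a pseudocount of 0.1 the counts are 1115 and 1175.

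In the CTCF overexpression libraries of day 10, pluripotency genes stood higher and keratinocyte and epithelial genes lower than in the 1 control sample. The control has no spread of its own. All p of this contrast, those adjusted over a list alone included, take their spread from the 2 treated groups. No list call stands with the correlation estimated. Ctcf itself stood 2.16 higher (SE 0.25, adjusted p = 0.217) and Smarca5 0.19 higher (adjusted p = 0.849). Neither passes. The factors Myc, Pou5f1, Sox2 and Klf4 stood at -0.26, -0.18, -0.40 and -0.16. In the pluripotency list 11 of 26 genes rose and 0 fell when adjusted over the list alone, against 0 over all genes (median 0.65). They include Lin28a (2.59, SE 0.20, 362 against 59), Dnmt3l (2.13), Esrrb (1.71, 893.5 against 273) and Dppa5a (1.39). Of 7 keratinocyte genes, 5 fell adjusted over the list alone (median -0.87), with Krt6a at -1.18 (SE 0.32), Krt14 at -0.94, Krt5 at -0.88 and Krt17 at -0.87 (7779 against 14206). Of 20 epithelial genes, 2 fell adjusted over the list alone (median -0.57), and Cldn7, Rab25 and Esrp2 stood at -0.96, -0.96 and -0.95. Cell cycle genes had a median of 0.39, with the replication licensing gene Mcm2 at 0.68 and Ccnb1 at 0.44, and 0 of them passed.

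Called were 8 genes, all higher: Trdn, Sim1, Rab9b, Ifnk and Mmp20, which the control lists at 0, Fam227b (169 against 1.5), Rgs1 (314 against 8) and the pheromone receptor gene Vmn2r85 (398 against 16), whose family has close copies. They lie outside the naming rule and were chosen after their values were seen. The count is not stable: 35 and 65 without D10_oeCTCF replicate 1 or replicate 2, 28 and 15 without D10_oecontrol replicate 1 or replicate 2, and 1 with a pseudocount of 8. List tests were called for pluripotency (adjusted p = 8.89e-12), cell cycle (1.44e-10), epithelial (1.29e-09), keratinocyte (7.84e-08), matrix (median -0.17, 0.00160; Col5a1 -0.54, Lox -0.53), trophoblast (-0.46, 0.0102; 1 lower adjusted over the list alone) and CTCF, cohesin and ISWI genes (0.08, 0.0122; 1 higher adjusted over the list alone). MEF-high and iPSC-high genes were called at -0.10 (0.00123) and 0.16 (0.000203; 3 higher adjusted over the list alone). With the correlation estimated these calls end: for pluripotency genes adjusted p = 0.636 with an estimated correlation, and for keratinocyte genes adjusted p = 0.591 with an estimated correlation. No call was made for mesenchymal (median -0.11), p53 (0.03), AP-1 (-0.04), interferon (-0.09), protocadherin (-0.00), Hox (-0.14), imprinted (-0.04), endoderm (0.10), neural (0.10), smooth muscle (-0.23), macrophage (-0.08) or factor genes (-0.22).

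The added Smarca5 shRNA was set against CTCF overexpression alone, a contrast that shares the overexpression libraries with the one above, so that opposite signs are given by their noise as well. Smarca5 stood 1.06 lower than with CTCF overexpression alone (log2 -1.06, SE 0.07, adjusted p = 0.0695), and Ctcf stood at 0.13, Pou5f1 at -0.02, Sox2 at 0.25, Klf4 at 0.17 and Myc at 0.07. Lin28a and Dnmt3l stood at -0.93 (SE 0.16) and -0.65, within a pluripotency median of -0.21, and the keratin gene Krt18 and the claudin genes Cldn3 and Cldn7, which seal epithelia, at 0.72, 0.68 and 0.62, within an epithelial median of 0.36. Krt7 stood at 0.65 in the trophoblast list (0.26), and it was the 1 gene there that rose adjusted over the list alone.

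Called were 10 genes, 5 each way. Higher were Ccr2 (309 against a level listed at 0), BB287469, 4930429F24Rik, Vmn2r83 and Vmn1r14, and lower Fstl5, Il1f8, 4933400A11Rik, Vmn1r4 and Gm14408, all outside the naming rule and chosen after their values were seen. Without D10_oeCTCF_shSmarca5 replicate 1 or replicate 2, or after quantile normalization, 0 are called, and without D10_oeCTCF replicate 1 or replicate 2 the counts are 40 and 44. List tests were called for epithelial (adjusted p = 5.65e-17), pluripotency (1.07e-07), protocadherin (median -0.11, 3.21e-08), cell cycle (-0.14, 1.93e-07), interferon (0.16, 0.000328) and trophoblast genes (0.00290). With the correlation estimated these end: for epithelial genes adjusted p = 0.746 with an estimated correlation. The comparison with the control, given next, uses 1 control sample without spread of its own. Its calls, those adjusted over a list alone included, rest on the spread of the treated groups. Against the control, the double treatment had 13 called genes (9 higher and 4 lower), Ctcf at 2.30 (adjusted p = 0.208) and Smarca5 at -0.87 (adjusted p = 0.187), and the factors at -0.20 (Pou5f1), -0.16 (Sox2), 0.01 (Klf4) and -0.18 (Myc). Here too the count is 0 without D10_oeCTCF_shSmarca5 replicate 1 or replicate 2. Here pluripotency genes had a median of 0.39 (2 higher adjusted over the list alone; 9.95e-09, and adjusted p = 0.824 with an estimated correlation), keratinocyte genes -0.55 (3 lower adjusted over the list alone; 2.53e-08, and adjusted p = 0.534 with an estimated correlation) and cell cycle genes 0.19 (9.31e-06, and adjusted p = 0.824 with an estimated correlation).

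The fold changes of adding Smarca5 shRNA ran against those of CTCF overexpression across genes (r = -0.355). The 2 contrasts share the overexpression libraries, and simulated noise alone gave -0.512 to -0.298 (mean -0.419). Over genes above the median level r was -0.500, outside the simulated -0.455 to -0.352, with a covariance of -0.0129 against -0.0119 simulated. Among genes at unadjusted p, 45 were higher and then lower and 36 lower and then higher, against 2.62 and 3.00 expected for independent calls, which these are not.

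In the authors' deposited table for CTCF overexpression, Ctcf went from 2039 to 10177 (log2 2.32, p = 4.07e-69). It is of the same day 10 overexpression experiment that was fitted above, so it is not separate evidence. Its fold changes and those of the fit had r = 0.488 over 12934 genes (rank correlation 0.798). Whether its p takes the control columns as separate libraries is not stated. Moving with Ctcf were Dppa5a (1.32), Apoe (1.23), Fbxo15 (1.12), Esrrb (1.12), Apod (1.06), Utf1 (1.06), the DNA methyltransferase Dnmt3b (1.02) and Dpp4 (0.99). Against it moved Alox12b (-1.29), Krt6a (-1.27), Anpep (-1.22), Asprv1 (-1.22), Klk10 (-1.17), Myh14 (-1.16), Sprr2a2 (-1.16) and Ppl (-1.15), several of them genes of the epidermal barrier. Klf4 (-0.60) and Myc (-0.43) moved against Ctcf, while Pou5f1 (-0.12) and Sox2 (-0.25) did not pass in that table. The authors' deposited table gives p below 0.05 for 655 of 15027 genes with p below 1, 219 with and 435 against Ctcf. Pluripotency genes had 16 with and 0 against of 27 (median 0.64) and cell cycle genes 8 and 0 of 20 (0.39). Epithelial genes had 0 and 10 of 20 (-0.50) and keratinocyte genes 0 and 6 of 8 (-0.65). Among 10000 random lists, these medians stood at percentiles 100, 100, 0 and 0, in that order. MEF-high and iPSC-high genes had 4 and 14 of 188 and 37 and 6 of 191.

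In the authors' deposited table for day 10 Ctcf shRNA, the Ctcf scores were 2197 and 1730 (log2 0.34, p = 2.53e-07), a smaller contrast than in any sorted population. Signs here give the group with more Ctcf over the other. Higher with more Ctcf were AI662270 (1.15), Sh3bp5 (0.89), Ttc27 (0.88), Sostdc1 (0.82), Slc30a7 (0.81), Plcl1 (0.81), S100a1 (0.79) and Lrrc28 (0.78). Lower were Gpr50 (-1.65), Eya2 (-1.33), Nckap5l (-1.09), Ifi27l2a (-1.07), Sgf29 (-1.03), Zc3h11a (-0.99), Tcerg1l (-0.94) and Aldh16a1 (-0.88). The factors ran against Ctcf (Klf4 -0.70, Sox2 -0.57, Myc -0.28, Pou5f1 -0.20), and Nanog with it (0.68). The authors' deposited table gives p below 0.05 for 3421 of 18908 genes with p below 1, 1663 with and 1757 against Ctcf. Pluripotency genes had 19 with and 0 against of 28 (median 0.40), AP-1 genes 8 and 0 of 11 (0.22) and Hox genes 4 and 0 of 31 (0.35). Imprinted genes had 7 and 1 of 20 (0.12), interferon genes 0 and 10 of 15 (-0.40) and keratinocyte genes 0 and 5 of 8 (-0.33). The Hox count is not above the share over all genes. Among 10000 random lists, these medians stood at percentiles 100, 99.98, 100, 99.72, 0 and 0.01, in that order. MEF-high genes had 36 and 12 of 197 and iPSC-high genes 55 and 18 of 194. At p below 0.01 the table holds 2262 genes.

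In both of the authors' deposited tables pluripotency genes were higher and keratinocyte genes lower where Ctcf was higher. Other lists differed between the tables. Epithelial genes had 0 with and 10 against Ctcf (median -0.50) for overexpression but 6 and 3 (0.05) for shRNA. Matrix genes had 0 and 3 (-0.18) for overexpression but 6 and 3 (0.10) for shRNA. Across 12146 genes the overexpression fold changes and the knockdown fold changes from the authors' deposited table, oriented to less Ctcf, had r = -0.109 (rank correlation -0.133), and the authors' 2 tables had r = -0.151 over 15009 genes. At p below 0.05 in both of the authors' deposited tables, genes higher with overexpression and lower with knockdown numbered 85 (22.8 expected), lower and higher 118 (48.7 expected), higher in both 9 (24.4 expected) and lower in both 37 (45.6 expected). The tables hold separate libraries per the labels, and what spread their p measures is not stated.

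Averaged over the 11 sorted populations, Serpinb9, keratinocyte and smooth muscle genes rose with Ctcf knockdown, and Lbr and cell cycle genes fell. Ctcf fell by 1.11 (log2 -1.11, SE 0.03, 603 against 1354), and Smarca5 moved by -0.10 (adjusted p = 0.0215). The largest rises were Serpinb9 (1.71, SE 0.06, 1866 against 633, GRCm38 13:33003250-33017957), an inhibitor of granzyme B, Elmod1 (1.16), Acta1 (1.09, 1014 against 657), Serpinb9b (1.00), Gvin1 (0.93), Tinagl1 (0.90), Serpinb8 (0.85), Vmn2r79 (0.85), Adh7 (0.84) and Nrk (0.82). Serpinb9 and Serpinb9b are close copies, as are members of the Gvin and Vmn2r families, so reads may be shared between them. The largest falls were Wasf3 (-1.30, SE 0.04), which drives actin branching, the lamin B receptor gene Lbr (-1.17, SE 0.03, 542 against 1177), Ctcf, Trpc5os (-1.10, SE 0.32, adjusted p = 0.00500, antisense to Trpc5), Nt5dc2 (-0.96), Spp1 (-0.91), Man2a2 (-0.85), N4bp2 (-0.84), Fbxo28 (-0.82) and Ltbp4 (-0.81). Serpinb9 ranged from 0.06 to 3.48 over the populations. The factors fell: Pou5f1 by -0.34, Klf4 by -0.26, Sox2 by -0.24 and Myc by -0.13 (adjusted p = 0.0112).

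Smooth muscle genes rose, 9 of 9 (median 0.47), with Cnn1 at 0.88, Acta2 at 0.48, Actg2 at 0.47 and Tpm2 at 0.36. All 4 keratinocyte genes rose (0.72), with Krt14 at 2.23, Krt6a at 0.81, Krt17 at 0.63 and the cell cycle inhibitor Sfn at 0.47. Cell cycle genes fell, 19 of 20 (-0.22), led by the ribonucleotide reductase gene Rrm2 (-0.80), Ccnb1 (-0.36), Top2a (-0.31) and Plk1 (-0.27). Pluripotency genes had 1 higher, 13 lower and 14 not passing of 28 (-0.23), among them Gdf3 (-1.03), Utf1 (-1.02), Mybl2 (-0.38) and L1td1 (-0.35). MEF-high genes, not independent as said, had 136 higher and 20 lower of 198 (139 and 21 adjusted over the list alone; 0.21), and iPSC-high genes 19 and 86 of 184 (-0.21). Matrix genes split, 13 higher and 6 lower (0.18), with Col5a2 at 0.38 and Fbln2 at 0.32 but Col6a2 at -0.62 and Col6a1 at -0.34. Mesenchymal genes had 9 and 2 of 19 (0.20; Cdh2 0.48, Snai2 0.32, Vim 0.26, Prrx1 0.24), and Hox genes 14 and 0 of 30 (0.14; Hoxd13 0.63, Hoxa10 0.47, Hoxa11 0.46).

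Other lists moved in part. Clustered protocadherins, neighbours under CTCF control, had 19 higher and 2 lower of 28 (19 and 3 adjusted over the list alone; 0.07; Pcdhb19 -1.32, Pcdhb22 -0.48, Pcdhgb7 0.10); alpha and gamma members share constant exons and have nearly equal values. The CTCF, cohesin and ISWI list had 2 and 8 of 20 (2 and 9 adjusted over the list alone; -0.05; Stag1 0.39, Rad21 -0.23, Baz1a 0.20). Epithelial genes had 5 and 4 of 20 (-0.00; Dsp 0.45, Krt19 0.25, Lsr -0.77), p53 genes 9 and 1 of 15 (0.11; Cdkn2b 0.57, Mdm2 0.17, Cdkn1a 0.17, Sesn2 -0.12), AP-1 genes 4 and 5 of 11 (-0.01; Fosl2 0.26, Fos -0.31, Egr1 -0.37) and interferon genes 5 and 1 of 10 (6 and 1 adjusted over the list alone; 0.25; Ifih1 0.86, Ifit2 0.63). Imprinted genes had 8 and 2 of 18 (0.06; Plagl1 0.74, Peg3 0.44, Nnat -0.72), trophoblast genes 4 and 0 of 8 (0.29; Krt7 0.71, Plet1 0.37), endoderm genes 2 and 1 of 5 (0.06; Cubn 0.51, Lama1 -0.31) and neural genes 4 and 0 of 6 (0.21; Neurog2 0.70, Map2 0.22). Skeletal muscle genes had 2 and 0 of 4 (0.26; Des 0.35), endothelial genes 2 and 0 of 4 (0.09; Kdr 0.74, Tek 0.23) and macrophage genes 3 and 5 of 10 (-0.23; Lyz2 -0.62, Laptm5 -0.36).

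The mean effect had 6993 called genes, 3526 higher and 3467 lower, of which 60 and 57 moved at least 2-fold. List tests were called for MEF-high (adjusted p = 1.26e-13), cell cycle (1.82e-10), smooth muscle (2.26e-07), iPSC-high (2.91e-06), keratinocyte (0.000482), pluripotency (0.00346), Hox (0.0127, and adjusted p = 0.146 with an estimated correlation), mesenchymal (0.0310, and adjusted p = 0.126 with an estimated correlation) and factor genes (0.0465, and adjusted p = 0.251 with an estimated correlation). The Myc call ends without day 9 Thy1+ cells (0.01, adjusted p = 0.818), day 6 DN cells (adjusted p = 0.0570) or day 9 DN cells (adjusted p = 0.145), and that of Sox2 without day 9 Thy1+ cells (-0.11, adjusted p = 0.115). That of Smarca5 ends without day 6 DN (adjusted p = 0.0869), day 9 DN (0.0838) or day 12 cells (-0.08).

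At day 3 keratinocyte genes rose with Ctcf shRNA, and at day 0 the list had 1 higher and 1 lower of 4 (1 and 2 adjusted over the list alone; median -0.31, adjusted p = 0.604). Krt14, a basal epidermal keratin, moved by 0.38 at day 0 and rose by 2.32, 4.12 and 3.15 in Thy1+, SSEA1+ and DN cells of day 3, in the last from 13.5 to 126. With it in day 3 DN cells rose Krt17 (2.10), Krt6a (1.67) and Sfn (0.85). Adjusted over the list alone all 4 genes rose in the 3 day 3 populations, and over all genes 3, 3 and 4 (medians 1.33, 1.37 and 1.89). Of 20 cell cycle genes, 8 fell in Thy1+, 3 in SSEA1+ and 3 in DN cells (9, 3 and 8 adjusted over the list alone; -0.28, -0.15 and -0.20). Epithelial genes had 5 higher and 1 lower at day 0 (6 and 1 adjusted over the list alone; 0.33), 4 and 1 in day 3 SSEA1+ (0.30) and 4 and 1 in DN cells (0.53), where Esrp1 (1.58), Cldn4 (0.91) and Dsp (0.81) rose and the tricellular junction gene Lsr fell (-1.26). In SSEA1+ cells 5 of 11 AP-1 genes rose (8 adjusted over the list alone; 0.31, list adjusted p = 1.62e-07), and 2 of 10 macrophage genes fell in Thy1+ cells (4 adjusted over the list alone; -0.91, list adjusted p = 0.0194). At day 0 the factors stood at -0.65 (Pou5f1, adjusted p = 0.0435), -0.55 (Sox2), -0.49 (Klf4, adjusted p = 0.0414) and 0.35 (Myc), and both calls end without D0_shCTCF replicate 2 (adjusted p = 0.768 and 0.331), while without D0_shCTCF replicate 1 Sox2 (-0.97) and Myc (0.52) pass. At day 3 none passed: Pou5f1 0.06, 0.10 and 0.17, Sox2 0.09, 0.30 and 0.13, Klf4 0.06, 0.05 and 0.22 and Myc 0.15, 0.36 and 0.28 in Thy1+, SSEA1+ and DN cells.

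Called genes numbered 898 at day 0 (394 higher, 504 lower), and 541, 912 and 657 in day 3 Thy1+, SSEA1+ and DN cells. The keratinocyte tests had adjusted p of 6.70e-09, 3.34e-08 and 1.80e-10, and the cell cycle tests 4.54e-14, 0.000167 and 5.25e-08. Without D0_shCTCF replicate 2 day 0 has 227 calls, and without D0_shCTCF replicate 1 it has 2985. The day 3 counts fall to 223, 456 and 285 without D3_shLuci_Thy1+ replicate 1, D3_shLuci_SSEA1+ replicate 1 and D3_shCTCF_DN replicate 2, and to 0, 13 and 17 with the 2 groups fitted alone.

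At day 6, DN cells with Ctcf shRNA had more fibroblast RNA. Thy1 RNA stood at 584.5 ± 37.5 against 208 with control shRNA, in a gate meant to lack Thy1. Other cells that passed this sort were not tested for and are not excluded. Col1a1 rose from 7438.5 to 20854 (log2 1.49), with Col5a2 (1.37), Fbln2 (1.32), Thy1 (1.48), Cdh2 (1.17), Vim (0.90) and the calponin gene Cnn1 (2.29), and Nanog stood at 54.5 against 215. Matrix genes had 18 higher and 1 lower of 20 (median 1.08), mesenchymal genes 17 and 1 of 19 (0.93), smooth muscle genes 9 of 9 (1.44) and protocadherins 21 and 0 of 28 (21 and 1 adjusted over the list alone; 0.59). Keratinocyte genes rose, 4 of 4 (1.51; Krt14 3.21). Pluripotency genes had 2 higher and 13 lower of 28 (-0.57), with Utf1 at -2.94, Tet1 at -1.73, Mybl2 at -0.87 and L1td1 at -0.84, and cell cycle genes 18 lower (19 adjusted over the list alone; -0.53). In Thy1+ cells 8 of 11 AP-1 genes fell (9 adjusted over the list alone; -0.46), 7 of 20 matrix genes fell (9 adjusted over the list alone; -0.28) and 4 of 4 keratinocyte genes rose (1.64). In SSEA1+ cells 9 of 19 mesenchymal genes rose (12 adjusted over the list alone; 0.43), as did smooth muscle genes, 6 of 9 (7 higher and 1 lower adjusted over the list alone; 0.56). Of the factors, Pou5f1 (-0.52), Klf4 (-0.47) and Myc (-0.45) fell in DN cells and Sox2 stood at -0.44, whereas in Thy1+ and SSEA1+ cells none passed (Pou5f1 -0.07 and -0.11, Sox2 0.14 and 0.22, Klf4 -0.09 and -0.01, Myc 0.09 and -0.01). The DN calls of Klf4 and Myc end without D6_shCTCF_DN replicate 1 (-0.30 and -0.23, adjusted p = 0.189 and 0.265) and that of Pou5f1 without D6_shLuci_DN replicate 2 (-0.47, adjusted p = 0.149), while Sox2 passes without D6_shCTCF_DN replicate 2 (-0.63).

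Called genes numbered 5659 in DN (2717 higher, 2942 lower), 2980 in SSEA1+ and 1936 in Thy1+ cells. With the 2 groups fitted alone SSEA1+ and Thy1+ cells have 13 and 527, and they have 1787 without D6_shCTCF_SSEA1+ replicate 2 and 958 without D6_shCTCF_Thy1+ replicate 2. Calls in DN cells included matrix (adjusted p = 9.91e-13), protocadherin (3.29e-10, and adjusted p = 0.148 with an estimated correlation), smooth muscle (1.86e-09), cell cycle (8.35e-10), mesenchymal (7.40e-08), keratinocyte (0.00222) and pluripotency genes (0.0200). In Thy1+ cells AP-1 (4.85e-11), keratinocyte (1.69e-05) and matrix genes (2.08e-07, and adjusted p = 0.130 with an estimated correlation) were called. In SSEA1+ cells mesenchymal (0.000257, and adjusted p = 0.0633 with an estimated correlation) and smooth muscle genes (0.00175, and adjusted p = 0.186 with an estimated correlation) were called.

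**Figure D3:**
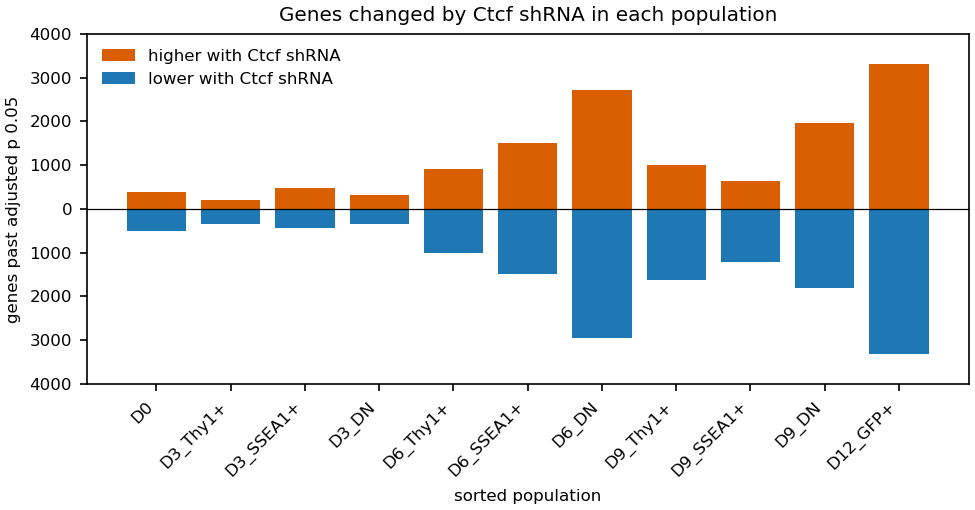
Genes called higher and lower with Ctcf shRNA in each of the 11 populations. The counts run from 541 in day 3 Thy1+ cells to 6624 in day 12 GFP+ cells.

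At day 9 the Thy1+ and SSEA1+ cells moved in different directions. In Thy1+ cells the 4 factors fell: Myc from 5387 to 1850 (log2 -1.54, SE 0.14), Pou5f1 from 2643.5 to 822 (-1.70), Sox2 by -1.57 and Klf4 by -1.16. Pluripotency genes had 12 lower and 0 higher of 28 (16 adjusted over the list alone; median -1.30), with Sall4 at -2.33, Mybl2 at -1.53, L1td1 at -1.34 and Trim71 at -1.07, and epithelial genes 14 lower of 20 (17 adjusted over the list alone; -1.47), with Cldn4 at -1.67, Krt8 at -1.64 and Esrp2 at -1.61. Cell cycle genes had 15 lower (17 adjusted over the list alone; -0.45), Hox genes 8 higher (10 adjusted over the list alone; 0.41) and smooth muscle genes 6 higher (8 adjusted over the list alone; 0.42).

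In day 9 SSEA1+ cells fibroblast genes fell. Col1a1 stood at 5346.5 against 12428, Thy1 at 446.5 against 1341.5 (-1.60), and Col6a2 (-1.72), Col1a2 (-1.66), Col6a1 (-1.50), Zeb1 (-1.22), Loxl2 (-1.14) and Vim (-0.72) fell. Matrix genes had 19 lower of 20 (20 adjusted over the list alone; -1.18), mesenchymal genes 13 of 19 (15 adjusted over the list alone; -0.79), protocadherins 24 of 28 (-0.54) and AP-1 genes 10 of 11 (11 adjusted over the list alone; -0.71), with Atf3 at -1.21, Fos at -1.17, Egr1 at -1.17 and Jun at -0.77. Zfp296 (0.56) and Mybl2 (0.22) rose in the pluripotency list (0 adjusted over the list alone; 0.40). In DN cells Thy1 RNA also differed, at 1426 ± 119 with Ctcf shRNA against 3012.5 ± 265 with control shRNA. These DN cells had 7 pluripotency genes lower and 1 higher (median -0.58). Of the factors 3 were lower (4 adjusted over the list alone, median -0.64), with Klf4 at -0.70, Sox2 at -0.66, Myc at -0.62 and Pou5f1 at -0.50 not passing. Cell cycle genes had 18 lower (19 adjusted over the list alone, median -0.49), and protocadherins 21 higher (21 and 2 lower adjusted over the list alone, median 0.33). The Sox2 call there ends without D9_shLuci_DN replicate 2 (-0.57, adjusted p = 0.0747). In SSEA1+ cells no factor passed (Pou5f1 0.03, Sox2 -0.04, Klf4 -0.13, Myc -0.13).

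Called genes numbered 2641 in Thy1+ (1010 higher, 1631 lower), 1861 in SSEA1+ (645 higher, 1216 lower) and 3763 in DN cells. With the 2 groups fitted alone they have 257, 13 and 2424, and the lowest counts without 1 library are 1572 (D9_shLuci_Thy1+ replicate 1), 1135 (D9_shCTCF_SSEA1+ replicate 1) and 2192 (D9_shLuci_DN replicate 1). In Thy1+ cells the epithelial (adjusted p = 8.73e-16), cell cycle (2.17e-11), factor (1.29e-07) and pluripotency tests (2.07e-07) were called, and smooth muscle genes (8.21e-05, and adjusted p = 0.0548 with an estimated correlation). In SSEA1+ cells the matrix (1.52e-35), protocadherin (9.06e-24), AP-1 (1.79e-16) and mesenchymal tests (2.67e-14) were called. The protocadherin value is too small, since alpha and gamma members share constant exons. In DN cells factor genes (0.00799, and adjusted p = 0.231 with an estimated correlation) and protocadherins (4.46e-07, and adjusted p = 0.283 with an estimated correlation) were called.

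At day 12, GFP+ cells with Ctcf shRNA had less pluripotency and more fibroblast RNA. Nanog stood at 3330.5 ± 26.2 against 5263 ± 358, Esrrb at 2407 ± 32.5 against 4213 ± 339, Thy1 at 1441 ± 41.0 against 615.5 ± 79.9 and Col1a1 at 15575 ± 198 against 4364 ± 25.5 (log2 1.84, SE 0.11). The imprinted RNA H19 stood at 39602 against 9443 (2.07, SE 0.10), with Igf2 (2.22), Peg10 (2.13) and Plagl1 (1.55). Pluripotency genes had 11 lower and 0 higher of 28 (11 adjusted over the list alone; median -0.78), with Klf5 at -0.75, L1td1 at -0.71, Klf2 at -0.69 and Mybl2 at -0.59, and of the factors Pou5f1 fell (-0.55, adjusted p = 0.021), with Sox2 at -0.27, Klf4 at -0.08 and Myc at 0.12.

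Matrix genes had 19 higher of 20 (20 adjusted over the list alone; 1.43; Col5a2 1.77, Fbln2 1.64, Col6a1 1.33), mesenchymal genes 17 of 19 (1.47; Cdh2 2.11, Prrx1 2.06, Vim 1.74, Cd44 1.56) and smooth muscle genes 9 of 9 (1.73; Acta2 2.00, Tagln 1.73, Tpm1 1.30). Hox genes had 22 higher and 1 lower of 30 (23 and 1 adjusted over the list alone; 1.06; Hoxa11 2.96, Hoxc8 1.99, Hoxd13 1.52), protocadherins 22 higher (0.85), imprinted genes 13 of 18 (13 and 1 lower adjusted over the list alone; 0.72) and AP-1 genes 9 higher and 1 lower (0.84). Epithelial genes had 6 higher of 20 (0.31; Krt18 1.90, Krt8 1.61, Krt19 1.43, Dsp 1.07), trophoblast genes 4 of 8 (5 adjusted over the list alone; 0.94), p53 genes 7 of 15 (0.41; the CDK inhibitors Cdkn2b 1.84 and Cdkn1a 0.82). Cell cycle genes had 19 lower of 20 (-0.54; Rrm2 -1.07, Mcm2 -0.63, Ccnb1 -0.61). MEF-high genes had 172 higher and 5 lower (175 and 7 adjusted over the list alone) and iPSC-high genes 10 and 60 (10 and 56 adjusted over the list alone), neither list independent of the study.

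Called genes numbered 6624, 3308 higher and 3316 lower, and 1276 and 332 moved at least 2-fold. List tests were called for matrix (adjusted p = 2.09e-17), protocadherin (3.41e-13, and adjusted p = 0.0555 with an estimated correlation), mesenchymal (5.12e-11), smooth muscle (1.01e-08), cell cycle (4.42e-09), Hox (3.41e-07), AP-1 (7.48e-06), imprinted (1.86e-05), pluripotency (0.000268) and p53 genes (0.0255, and adjusted p = 0.0555 with an estimated correlation). Without D12_shLuci_GFP+ replicate 1 the Pou5f1 call ends (adjusted p = 0.0903).

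**Figure D4:**
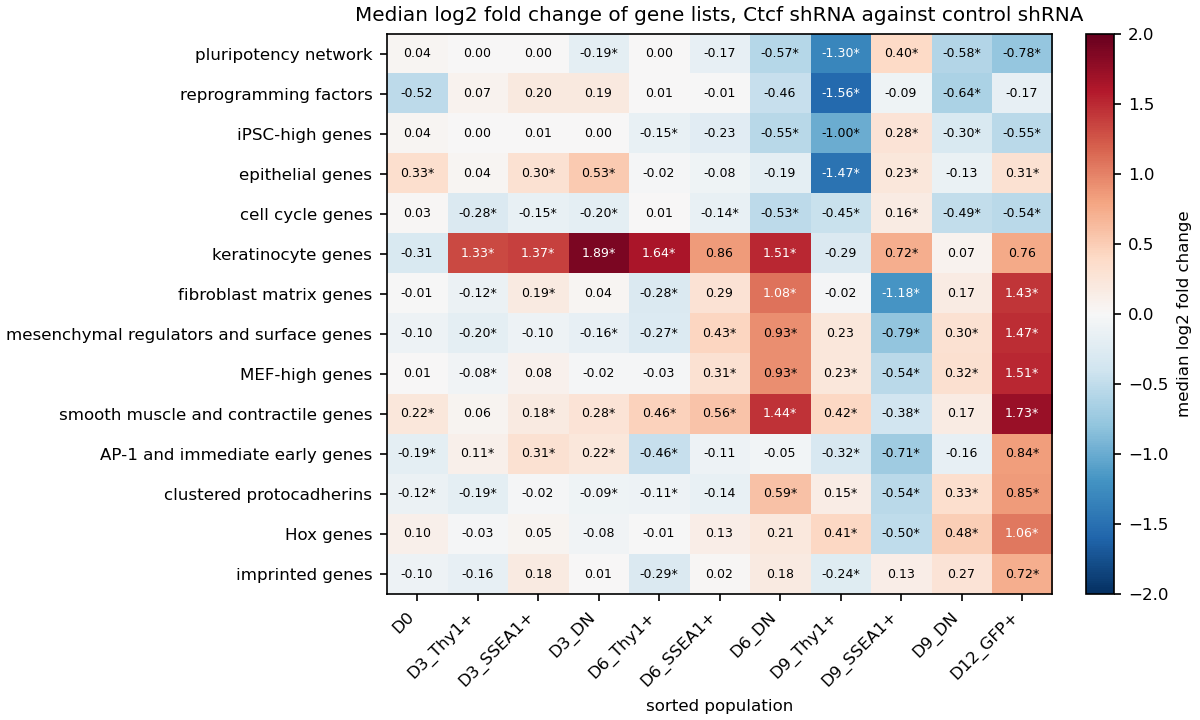
Median log2 fold change of each gene list with Ctcf shRNA in each of the 11 populations, with asterisks at an adjusted list p below 0.05. Matrix genes stand at 1.43 in day 12 GFP+ cells and at -1.18 in day 9 SSEA1+ cells.

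The measured knockdown effect therefore differed between populations. In day 6 DN, day 9 SSEA1+ and day 12 cells, other cells that passed the sort are not excluded as a part of this difference. The 6 genes with the strongest differences were the growth factor gene Ereg (F = 118.84, adjusted p = 2.97e-15, from -1.35 in day 9 SSEA1+ to 2.06 in day 12 cells), Il1rl1 (F = 112.61, -1.18 to 2.14), Vcam1 (F = 94.681, -0.59 to 1.90), Gsn (F = 93.31, -0.35 to 1.84), Fgf7 (F = 88.861, -1.74 to 1.39) and Col6a1 (F = 87.002, -1.50 to 1.33). In all 7530 genes were called in this test.

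Over days 3, 6 and 9, epithelial and iPSC-high genes fell less, or rose more, with Ctcf shRNA in SSEA1+ than in Thy1+ cells. The difference (SSEA1+ minus Thy1+) was 1.06 for Esrp1, 1.03 for Krt8 and 0.64 for the splicing regulator Esrp2, with 10 epithelial genes higher of 20 (12 adjusted over the list alone; median 0.66). Pluripotency genes had 4 higher (5 adjusted over the list alone; 0.32; Tfcp2l1 1.29, Trim71 0.73, Mybl2 0.65, L1td1 0.48), the 4 factors were higher (0.54; Sox2 0.60, Pou5f1 0.58, Myc 0.51, Klf4 0.37) and imprinted genes had 6 higher (7 adjusted over the list alone; 0.22; Meg3 0.71, Mest 0.68, Igf2 0.62). Ctcf and Smarca5 stood at -0.13 and -0.01. Protocadherins had 1 higher and 6 lower (1 and 11 adjusted over the list alone; -0.18), and iPSC-high genes 56 and 3 (71 and 3 adjusted over the list alone; 0.43), the latter not independent.

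This difference had 1305 called genes, 728 higher and 577 lower. List tests were called for iPSC-high (adjusted p = 1.34e-17), epithelial (3.04e-10), imprinted (6.58e-05), pluripotency (0.000348) and factor genes (0.000348, and adjusted p = 0.0909 with an estimated correlation). List tests were not run without day 9. SSEA1+ cells in the day 9 control Thy1+ libraries are not excluded as a source of the epithelial difference. Without day 9 the factor calls end (Myc 0.05, adjusted p = 0.898, and Sox2 0.14, adjusted p = 0.768) and the count is 572. Without D3_shCTCF_Thy1+ replicate 2 those of Klf4 (0.28, adjusted p = 0.116) and Pou5f1 (0.48, adjusted p = 0.0539) end.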

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

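All artifact tests below were written and chosen only after the results they concern had been seen. They weigh 3 patterns found in the sorted cells.

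In day 12 GFP+ cells with Ctcf shRNA, MEF-high genes rose, as did Col1a1, and iPSC-high genes fell. A bias of GC content or gene length may shift such lists, yet with both trends removed from each library the MEF-high median was 1.45 (quartiles 0.99 to 1.84), which argues against it. Fibroblast-like cells that passed the Oct4-GFP sort, a gate meant to remove them, are another explanation. The gain per gene ranked with the Thy1+ level (0.938) about as closely as with the control GFP+ level (0.943), a difference of -0.0056343 (95% interval -0.032 to 0.023, 113 genes), which leaves this open. The iPSC-high genes need a median share of 0.34861 of such cells (quartiles 0.212 to 0.472) and the MEF-high genes 0.133 (0.0918 to 0.182). Only members more than 8-fold apart between source and control, with a level above 500, were used. These were 110 iPSC-high genes, of which 98 had a share above 0 (lowest -0.651), and 113 MEF-high genes, all 113 above 0. With day 9 DN cells as source the shares are 0.458 (0.361 to 0.553, 56 genes) and 0.275 (0.249 to 0.347, 37 genes). The quartiles do not overlap with either source, but both sources are from another day, so this stays open too.

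In day 9 Thy1+ cells the 4 factors fell together with Ctcf shRNA. They could fall as 1 transcript of the vector. Their fold changes over the 11 populations had a mean correlation of 0.89388, with 0 of 10000 random sets of 4 genes as high. Without day 9 Thy1+ and DN cells it was 0.587 (145 of 10000 as high). Genes that move together for any other reason would also exceed random sets, so this cannot single out the vector. SSEA1+ cells in the control Thy1+ libraries could raise the factors there. Yet the factors need a share of at least 0.26217 and no epithelial gene needs more than 0.137 (median 0.0920, 17 genes). This argues against it for the factors. The epithelial genes need similar shares (quartiles 0.075 to 0.111), so such cells are not excluded for their own fall. Cells with neither marker in these libraries would need a median share of 0.26313 for the factors. For epithelial genes it was 0.201 to 0.233 (quartiles, highest 0.259, 13 genes), which leaves that open. Such cells lack Thy1 by gate label only: control day 9 DN libraries had Thy1 RNA at 3012.5 ± 265, against 3121 ± 72.1 in day 0 control cells.

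In day 9 SSEA1+ cells MEF-high genes fell with Ctcf shRNA, and so did Thy1 and Col1a1. Thy1+ cells in the control SSEA1+ libraries may explain it. The excess per gene ranked with the Thy1+ level more closely than with the knockdown SSEA1+ level, by 0.033328 (95% interval 0.0132 to 0.0653). This rank comparison cannot decide. The knockdown level is itself subtracted in the excess, and the genes were chosen for a high Thy1+ level, which both favour the Thy1+ rank. The median share needed was 0.0766 over 65 genes, and 0.0743 and 0.0782 in the 2 libraries. The iPSC-high genes need 0.33421 (quartiles 0.212 to 0.393, 23 genes) against quartiles of 0.0619 to 0.0921 for MEF-high genes, which argues against Thy1+ cells as the source of their rise. Sort purity is not recorded in the labels.

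Other results stand as values. The knockdown effect differed between populations for 7530 genes, with F = 118.84 for Ereg, 112.61 for Il1rl1, 94.681 for Vcam1, 93.31 for Gsn, 88.861 for Fgf7 and 87.002 for Col6a1. It differed between SSEA1+ and Thy1+ cells for 1305 genes. In this difference the factors stood at 0.51 (Myc), 0.58 (Pou5f1), 0.60 (Sox2) and 0.37 (Klf4). List medians in this difference were 0.32 for pluripotency, 0.54 for factor, 0.66 for epithelial, 0.12 for CTCF, cohesin and ISWI, 0.16 for cell cycle, -0.18 for protocadherin, -0.23 for Hox, 0.22 for imprinted, -0.25 for smooth muscle, -0.0873 for MEF-high and 0.43 for iPSC-high genes. Repeat types called were 62 in the mean knockdown effect and 491 between day 12 and day 0. In 100 label splits, the real one included, the mean effect had 6993 calls against 1221 in the highest other split. The SSEA1+ against Thy1+ difference had 1305 against 271 and the interaction 7530 against 5474, so 1 of 100 splits reached each value. Splits that mix the arms turn a real difference into spread, which lowers their counts. They also cannot exclude chance differences between cultures, because replicates may share a culture.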

How the results depend on the processing

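Alternatives added after the data were seen are the mean level of at least 100, groups fitted alone, omitted populations or days, the replicate block for lists and the stricter authors' p. The fit with separate controls is the planned one, and averaging them was chosen after the values were seen.

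Of 395 settings over 29 results, 327 kept the count within 1.5 times and 68 moved it. Counts have no direction, so only the correlations could turn, and 0 did. The settings without the gene filter repeat the main fit, since every gene met the filter. They are among the 327, so that number overstates how stable the counts are. Quantile normalization starts from libraries that already share nearly the same distribution, so it is a weak check of the normalization. CTCF overexpression against control (8 calls) gave 56 without the trend, 2 with a replicate block, 1 with a pseudocount of 8, 141 with both control columns as separate libraries and 5 at a mean level of at least 100. Added Smarca5 shRNA against overexpression (10 calls) gave 31 without the trend, 0 after quantile normalization, 0 with the block and 0 at the higher level. Both treatments against control (13 calls) gave 51, 5, 2, 1 with a pseudocount of 8, 74 with separate controls and 6 at the higher level.

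With the 2 groups fitted alone, Ctcf shRNA gave 4 calls at day 0, 0, 13 and 17 in Thy1+, SSEA1+ and DN cells of day 3, 527 and 13 in Thy1+ and SSEA1+ cells of day 6, and 257, 13 and 2424 in Thy1+, SSEA1+ and DN cells of day 9. Without day 9 the SSEA1+ minus Thy1+ difference had 572. The authors' shRNA table had 2262 genes at p below 0.01. MEF against iPSC had 2290 genes with a pseudocount of 0.1 against 1342. The correlation of the contrasts that share libraries was -0.50 above the median level. Myc turned to 0.014 in the mean effect without day 9 Thy1+ cells, and Pou5f1 to -0.0010021 in the SSEA1+ minus Thy1+ difference without day 9.

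Without 1 library the counts ran from 6789 to 7167 for the mean effect, 6749 to 8565 for the interaction and 1035 to 1473 for the SSEA1+ minus Thy1+ difference. They ran from 227 to 2985 at day 0, 223 to 405, 456 to 577 and 285 to 324 in Thy1+, SSEA1+ and DN cells of day 3, 958 to 1091, 1787 to 2714 and 4286 to 4472 at day 6, 1572 to 2263, 1135 to 1262 and 2192 to 2618 at day 9, and 5038 to 5348 at day 12. SSEA1+ against Thy1+ had 7670 to 7712, 9553 to 9588 and 8222 to 8500 at days 3, 6 and 9. Against day 0 SSEA1+ cells had 8914 to 9039, 9666 to 9753 and 9039 to 9126, and day 12 cells 10210 to 10260. The day 10 contrasts had 15 to 65, 0 to 44 and 0 to 33. The block was kept as an alternative only, since pairing would need every one of 12 same-numbered pairs to correlate above 0.1: over all genes 0 did (-0.045 to 0.0714), and above the median level 8 did and 4 did not (-0.0516 to 0.715). A lone library was assumed to vary like the other groups.

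Of 250 list calls, 140 stood with the correlation estimated, 5 were lost and 3 gained after quantile normalization, and 1 was lost and 2 gained with the block. Of 146 calls for named genes, 12 ended without some single library, 3 without the trend, 2 after quantile normalization and 0 with the block or a pseudocount of 8. With the 2 groups alone 17 of 117 ended.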

Other observations

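The contents of this part were chosen only after the results had been seen. Repeat RNA also moved. In the mean knockdown effect 62 of 819 repeat types were called, 30 higher and 32 lower, and of the early transposons MMETn-int (-1.03, SE 0.053, adjusted p = 3.6e-14) and ETnERV-int (-0.81) fell, with RLTR13G (-0.83) and L1MEi (-0.37). IAPEz-int (0.32), IAPLTR1_Mm (0.29) and MER110A (0.41) rose, as did another early transposon, ETnERV3-int (0.28, adjusted p = 0.000555). MMETn-int fell most in day 9 Thy1+ (-2.22) and day 6 DN cells (-1.95), and ETnERV-int in the same populations (-1.67 and -1.68). With control shRNA these types rise on the way to day 12, RLTR13G by 6.24, L1MEi by 5.78, MMETn-int by 5.77 and ETnERV-int by 5.40, among 491 called types (363 higher, 128 lower). In the ERVK family 135 were higher and 14 lower of 211, and all 15 Alu (median 0.75) and 5 B2 types (1.34) were higher. CTCF overexpression had 0 of 933 types called.

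Neighbouring genes were weakly correlated. For the mean knockdown effect the correlation between adjacent genes was 0.114 at 10 to 50 kb (3400 pairs, highest of 1000 shuffles 0.0629), 0.0974 at 50 to 200 kb (2597 pairs, highest 0.0628) and 0.0502 beyond (1893 pairs, 27 of 1000 shuffles as high). At day 12 it was 0.140, 0.116 and 0.0738. From day 0 to day 12 with control shRNA it was 0.191, 0.187 and 0.0667, so the correlation is present without knockdown as well.

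Matrix genes stood at 1.43 with Ctcf shRNA in day 12 GFP+ cells, at 1.08 in day 6 DN cells and at -1.18 in day 9 SSEA1+ cells, where day and gate both differ, and Thy1+ cells in the control libraries of the last are not excluded. Other cells that passed the sort are not excluded in the day 12 and day 6 DN knockdown libraries either. Krt14 stood higher with Ctcf shRNA in all 11 populations, by 0.38 at day 0 to 4.12 in day 3 SSEA1+ cells. The labels do not give hairpin sequences, so off-target effects in the sorted cells were not analysed here. Measuring sorted purity, and the vector transcript apart from the genes of the cell, would settle the open points at day 9.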
